A study of Mus musculus with 4 samples.

How the data were processed

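Mouse brain organoids were grown from CARLIN/Cas9 embryonic stem cells seeded at 5000 cells per well, embedded in Matrigel and kept on an orbital shaker, per the labels' protocols. From day 9 the medium held 2% B27 with vitamin A or a retinoid ligand, and sections were made after 3 months. Several fixed organoids were frozen in a mold, so a section may hold more than a single organoid. Cryosections were placed on printed barcoded poly-T arrays, and the libraries were sequenced as paired ends on a NovaSeq, per the labels' protocols. The genome build was mm9, per the submitters' processing notes. The aligner, the counting of molecules and the filter on spots are not given in the sources used here. The monolayer single-cell and chromatin data of the series were not analysed here.

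The deposited values are a signal per gene and spot, quantile normalised over the spots of a section by the authors. This was checked on the values: every spot of a section holds the same sorted values times a factor of its own, and the highest factor of a section was between 25.6 and 43.7 times the lowest. Each spot of a section has the same number of positive genes, 8604 in VitaminA, 12291 in ATRA, 10270 in BMS753 and 12735 in BMS961+BMS641. Runs of values that rise with the order of genes were taken as equal ranks split by that order. The lowest run of a spot is its lowest class. In it, gene order and value had a median Spearman correlation whose lowest value over sections, in ATRA, was 0.998. The definition of the class fixed this correlation, so it is no check of the split, on which only the length of the run bears. Of the positive values, that class held 45.6% in VitaminA, 70.2% in ATRA, 64.9% in BMS753 and 63.2% in BMS961+BMS641, and of the signal 5.64%, 7.58%, 13.8% and 6.75%. The files hold no counts, so the depth of a spot is unknown and limits the precision by an unknown amount.

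The level of a gene was the mean of the deposited signal over all spots of a section, as ppm of the sum over genes. Log2 ratios of levels used a pseudocount of 1 ppm and genes of at least 5 ppm in either section. The groups are VitaminA, ATRA, BMS753 and BMS961+BMS641, and all 6 pairs were compared. With a single section per group, no p-value, standard error or number of changed genes was computed. Each section was split into 4 quadrants, at the median of x and then of y, and values were recomputed for the 16 pairs of quadrants. For 33 gene lists the members higher and lower, by the sign of their log2 ratio, were counted. The median log2 ratio and its percentile among 10000 random lists of the same size, matched on mean level, were computed. A list needed 3 measured genes, which the list of erythroid genes did not reach.

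Genes were named by a rule. Eligible were genes of at least 20 ppm in either section, above the lowest value in at least 5% of its spots, with all quadrants of a section above all of the other. Predicted genes, ribosomal protein genes and mitochondrial genes were left out, and no mitochondrial symbol was listed. The 8 eligible genes with the highest and the lowest log2 ratios were named, with up to 3 members of each list described. Another 9 genes were named always, whatever their level. The rule, the lists, the comparisons and most alternative settings were fixed before the data were examined. Which lists to describe by their members was chosen after the values were seen: the neuronal, astroglial, retinoid, progenitor, pluripotency and proliferation lists in every comparison with those of Hox groups 1 to 4, of transmitters and of reactive astroglia, and any list outside the central 95% of random lists. Some genes that the rule picked are not reported here, and are left out of the counts of values under alternative settings, also where their sign turned. Region leaders and the genes with most signal in a section were named from their values as well.

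Within sections, list scores were the mean over genes of z scores over spots of log2 of the signal plus 1. Moran's I used 8 grid neighbours and was set beside 100 random lists. Regions came from k-means with k = 4 on 20 principal components of the 2000 most variable genes. Genomic spans came from the reference annotation, to which 22097 of 22218 symbols were matched, and the other 121 were left out of steps that use span. The alternatives changed the scaling, the pseudocount, the filter, the summary over spots, the spots used, the neighbours and the number of regions. Others, chosen after the data were seen, set the lowest class at 0, used tie class indices, centred ratios within bins of level and span or left out the top 10 genes. The spot factor was divided out for the values within sections only. Levels and list medians were not recomputed in that way, though tie class indices do not hold the factor. The computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0 and matplotlib 3.10.9.

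The steps were tested on simulated data, in which 200 genes per section were raised or lowered by factors of 2 and 4 before a like quantile normalization. The sign was right for at least 99% of them. Changed genes were drawn from those at or above the median in mean tie class index. Each simulated section was compared with an unchanged simulated copy of itself, so differences between the profiles of real sections were not covered. Values were drawn as Poisson counts around the mean tie class index, as if it were a number of molecules. The true depth is unknown, and genes with most signal in a few spots were not simulated, so the recovery may be too high. In BMS753, as deposited, 81% of genes changed by a factor of 2 lay outside the central 95% of unchanged genes. From values as deposited, genes raised by a factor of 2, a true log2 ratio of 1, had median ratios from 0.95 to 1.02.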

Results

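Spatial transcriptomes were measured on cryosections of mouse brain organoids, tissues grown in suspension from embryonic stem cells that carry the CARLIN lineage barcode and Cas9. The organoids were 3 months old. From day 9 they had received either B27 supplement with vitamin A or agonists of the retinoic acid receptors, the nuclear receptors through which derivatives of vitamin A act on genes. ATRA, all-trans retinoic acid, activates all of these receptors. BMS753 is an agonist of receptor alpha, and BMS961 and BMS641, given together, are agonists of receptors gamma and beta. ATRA and BMS753 were given at 1 µM and the pair at 0.1 µM, so doses differed between the BMS compounds. Each of the 4 treatments has 1 section, so there are no replicates and no difference between treatments could be tested. The ranges in parentheses run over the 16 pairs of section quadrants of a comparison and describe variation within sections alone.

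The VitaminA section had 552 spots, the ATRA section 593, the BMS753 section 469 and the BMS961+BMS641 section 365. Between 20800 and 21639 genes were listed per section, and 19783 genes were listed in all 4. The number of reads or molecules behind a spot is unknown, so no counting interval can be given. As deposited, the sum of the signal over a spot had a median of 475573 in VitaminA, 266130 in ATRA, 293439 in BMS753 and 658643 in BMS961+BMS641. The lowest run of values that rise with the order of genes, called the lowest class of a spot here, was taken as ties split by that order. The median number of genes above that class in a spot was 4659 in VitaminA, 3388 in ATRA, 3330 in BMS753 and 4462 in BMS961+BMS641. Fam120a, Baz1b, Fhit and Pafah1b1 stood among the leading genes, and the top 10 genes of a section took between 12.6% and 16.5% of its signal.

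Detection followed the genomic span of genes closely. Across genes, which are not independent replicates, the Spearman correlation of span with the percent of spots above the lowest class was 0.834 in VitaminA, 0.803 in ATRA, 0.837 in BMS753 and 0.799 in BMS961+BMS641. Transcripts known to be abundant in most cells, such as those of cytoskeletal and translation genes, were seen in few spots. Their median percent of spots was 4.44 in VitaminA, 2.02 in ATRA, 2.45 in BMS753 and 2.47 in BMS961+BMS641. Levels of single genes are given as ppm of the signal of a section and carry this limit.

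**Figure D1:**
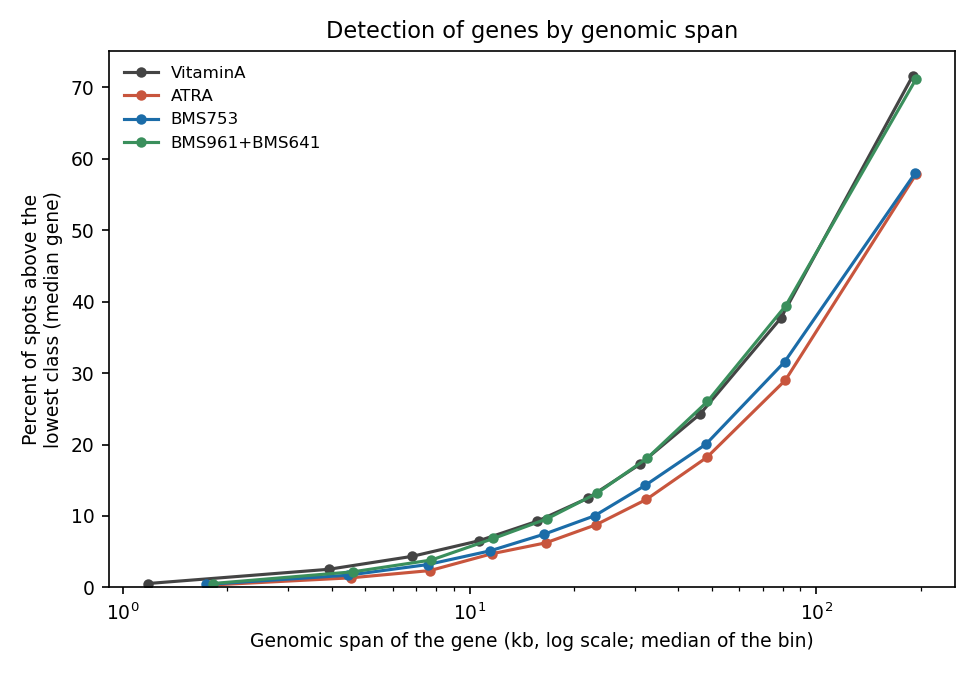
Percent of spots above the lowest class for the median gene (vertical axis) in bins of genomic span (horizontal axis, kb, log scale), with a line per section. The bin of the longest genes reaches 71.6 in VitaminA, 57.8 in ATRA, 58.0 in BMS753 and 71.2 in BMS961+BMS641.

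The first comparison asks how the organoids given the pan-receptor agonist ATRA differ from those given vitamin A. Genes that make, carry or reduce retinoids were lower with ATRA. Aldh1a2, which makes retinoic acid, stood at 16.3 ppm against 296 ppm, a log2 ratio of -4.10. Rbp4, the carrier of retinol in blood, had a log2 ratio of -3.80, and Dhrs3, which reduces retinaldehyde and is induced by retinoic acid in many tissues, of -2.95. Hoxb3, a hindbrain patterning gene of a cluster that responds to retinoic acid, was higher, at 169.8 ppm against 20.5 ppm (log2 ratio 2.99). Of the 5 measured genes of Hox groups 1 to 4, however, 3 were higher and 2 lower. That list lay inside the central 95% of random lists, at percentile 94.5. Neurog1, a proneural transcription factor, was lower at a log2 ratio of -6.35, but it was seen in 82.6% of VitaminA spots and at most 6.30% elsewhere, a pattern it shares with Lum and most genes of the lowest ratios. Also lower were Lhx6, a regulator of interneurons (-2.62), and Abat, which breaks down GABA (-2.22).

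By list, 19 of 23 measured retinoid pathway genes, all 16 GABAergic genes, 11 of 13 neural progenitor genes, all 11 pluripotency genes and 12 of 17 mesenchyme and matrix genes were lower with ATRA. The median log2 ratio over the 14794 genes compared was itself -0.33. Relative to it, the medians of these lists were -0.58, -0.66, -0.74, -0.95 and -0.67. They lay at percentiles 0.300, 2.45, 1.10, 0.230 and 0.460 among 10000 random lists of like level. With the lowest class at 0, the retinoid pathway list (-0.33, percentile 3.08), the neural progenitor list (-0.62, percentile 4.42) and the mesenchyme and matrix list (-0.34, percentile 5.27) lay inside the central 95% of random lists, and the microglia and macrophage list lay outside it, at 0.61 (percentile 98.5). Among random lists also matched on span, in the same setting, the microglia and macrophage list lay inside, at percentile 96.35. The pluripotency list lay inside these too, at percentile 4.795, while the GABAergic list stayed outside, at percentile 0.36. Sall4, a transcription factor of pluripotent cells, had -4.70, Dppa3, a germ cell and stem cell protein gene, -3.40, and Lum, a matrix proteoglycan gene, -3.38, but Col6a2, a collagen gene, had 2.59. As deposited, no other list lay outside the central 95% of the random lists. As the share of positive spots, which counts ties split by gene order as positive, Sall4 had 0.10, Lum 0.23 and Abat 0.41.

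Neither the neuronal nor the astroglial list lay outside the random lists with ATRA. The pan-neuronal median log2 ratio was -0.21 (-0.64 to -0.24, a range that leaves out the value of the whole sections), which is 0.12 relative to all genes, at percentile 59.8. Of its 19 genes 14 were lower, among them Elavl4, a neuronal RNA-binding protein gene (-2.55), Rtn1 (-1.98) and Map2, which encodes a protein of dendrites (-1.64). The astroglia median was -0.76 (-0.96 to -0.51), or -0.43 relative to all genes, at percentile 5.76, with 15 of 18 genes lower. With the lowest class at 0, the lists were at 0.35 and -0.16 relative to all genes. Nfib, a transcription factor of gliogenesis, had -1.79 and Acsl6 -1.87, while Mlc1, which encodes an astrocyte membrane protein, had 4.10. The neuronal median exceeded the astroglial median by 0.54, with a standard deviation of 0.13 over the pairs of quadrants. The pairs reuse the same quadrants, so that value describes spread within sections and is no error of the difference. That difference was 0.04 when only genes of at least 20 ppm were used, and 0.34 without quadrant 4 of ATRA.

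Among reactive astroglia genes, Osmr, the oncostatin M receptor gene, stood at 846 ppm against 15.2 ppm (5.71), and Stat3, a transcription factor of cytokine signalling, had 4.43, while the list as a whole lay at 0.17 relative to all genes. Among glutamatergic genes, 16 of 19 were lower, but the list was at -0.34 relative to all genes (percentile 5.36) and at -0.06 with the lowest class at 0 (percentile 23.8), with the receptor subunit genes Gria1 at -1.44 and Gria2 at -1.40. Of the receptor genes, Rara had -0.90, Rarg -1.74 and Rarb, itself a target of retinoic acid, -0.23, and Rarb was higher (0.10) once ratios were centred on all genes. The proliferation marker Mki67 had -2.72, Tubb3 -0.43, Slc1a3 -0.53 and Pou5f1 -0.23. Gfap, the astrocyte filament gene, was at 3.16 ppm against 3.84 ppm. It lay below the 5 ppm filter in every section, so its ratios in all comparisons rest on values near the floor.

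The largest ratios belonged to genes of unrelated function that were high over nearly the whole ATRA section. Pars2, a mitochondrial tRNA synthetase gene, was at 603 ppm against 1.30 ppm, and above the lowest class in 93.9% of spots against 3.08%. Its log2 ratio was 8.03, and next came U2af1 (8.01), Klhl28 (7.49), Lsm14b (7.35), Il9r (7.19), Cklf (7.07), Tut7 (6.96) and Fabp12 (6.93). U2af1 encodes a splicing factor and Il9r an interleukin receptor. The lowest ratios were those of Tmem52b (-7.77), Mocs2 (-7.34), Pgls (-7.26), Psmd9 (-6.86), Zfp239 (-6.73), Atp6v0b (-6.50), Cant1 (-6.49) and Mcrip1 (-6.47). Mocs2 serves the synthesis of the molybdenum cofactor and Psmd9 the assembly of the proteasome.

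The second comparison asks how the receptor alpha agonist BMS753 differs from vitamin A. Retinoid pathway genes were again low, with Rbp4 at a log2 ratio of -3.61 and Aldh1a2 at -2.82, while Tgm2, a transglutaminase gene, had 1.34. Neurog1, high over most of the VitaminA section alone, had -5.14, Dppa3 -2.94, Sall4 -2.53 and Lhx6 -2.18. Stmn2, which encodes a protein of growing axons, had 1.44, and Slc1a3, a glutamate transporter gene of astroglia, 1.01. The 3 comparisons with vitamin A share its section, so a gene that was high in that section alone was low in every one of them.

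The median log2 ratio over the 15676 genes compared was 0.31. Relative to it, the retinoid pathway list was at -0.60, at percentile 0.290, with 18 of 23 genes lower. The serotonergic list was at -0.73, at percentile 1.73, with 5 of 9 genes lower, but with the lowest class at 0 it was at -0.44, inside the random lists at percentile 7.96. Tph1, which encodes an enzyme of serotonin synthesis, had -1.76 and the serotonin receptor gene Htr2a 1.64. Hox groups 1 to 4 were at -0.90, but with 5 measured genes lay inside the random lists at percentile 3.87. No other list lay outside the central 95% of random lists as deposited, but with the lowest class at 0 the GABAergic list did, at -0.92 (percentile 0.100, 0.0300 of lists matched on span), with 12 of 16 genes lower, beside -0.50 (percentile 3.18) as deposited.

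Both lists lay inside the random lists with BMS753, and their members went both ways. The pan-neuronal median was 0.01 (-0.15 to 0.39), with 10 of 20 genes higher, and Elavl4 had -1.92 and Snap25, a gene of synaptic vesicle fusion, -1.36. The astroglia median was 0.06 (-0.32 to 0.44), with 10 of 18 genes higher, and Nfib had -1.31. Relative to all genes, both were lower, at -0.30 and -0.24, and lay at percentiles 16.4 and 19.4, and with the lowest class at 0 they were at -0.21 and -0.09. Their difference, -0.05, was smaller than its standard deviation over the pairs of quadrants (0.31). Among reactive astroglia genes, Ggta1 had 1.24 and Osmr 1.07.

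The highest ratios with BMS753 were those of Ap1g2 (4.74), Atp5h (4.71), Rpa2 (4.33), Chil6 (4.32), Iqcc (4.20), Aktip (4.17), Mov10 (4.17) and Fah (4.10). Fah, which encodes the last enzyme of tyrosine breakdown, was at 406 ppm against 22.7 ppm, and Rpa2 encodes a protein that binds single-stranded DNA. The lowest ratios were those of Mocs2 (-7.08), Tmem52b (-7.02), Tsga10ip (-6.53), Pgls (-6.37), Psmd9 (-6.24), Mcrip1 (-6.14), Atp6v0b (-6.01) and Eed (-5.81). Eed encodes a subunit of the Polycomb repressive complex. Among the receptor genes, Rara had -0.41, Rarb 0.06 and Rarg -0.63. Tubb3 had 0.72, Map2 -0.25, Mki67 -1.39, Pou5f1 0.15 and Gfap, below the 5 ppm filter in both sections, -0.54.

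The third comparison asks how agonists of receptors gamma and beta, given together, differ from vitamin A. Single neuronal genes were high in the BMS961+BMS641 section, although 15 of 19 pan-neuronal, 14 of 16 GABAergic and 14 of 19 glutamatergic genes were lower. Stmn2 stood at 533 ppm against 14.3 ppm, a log2 ratio of 5.13, and was above the lowest class in 97.3% of spots. Genes of unrelated function, such as Cym (98.4%), were seen as widely in this section, so such detection cannot by itself be read as neuronal. Gad1, which makes GABA, had 3.18, the glutamate receptor genes Grm5 and Gria3 had 2.55 and 2.24, and Crabp1, which encodes a cytoplasmic carrier of retinoic acid, had 4.14. Rbp4 (-4.62), Aldh1a2 (-3.33), Neurog1 (-5.68), Lhx6 (-3.58) and Tph1 (-4.61) were low, as in the other ligand sections.

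The median log2 ratio over the 14959 genes compared was -0.25. Medians of lists are given relative to it, while counts of lower and higher genes go by the sign of the ratio itself. The pan-neuronal list, with 15 of 19 genes lower, was at -0.45 (percentile 2.44). It lay inside the central 95% of random lists with the lowest class at 0 (-0.22, percentile 5.63). Without genes high over a single section it was at percentile 2.58, just inside. The list holds no such gene, so only the random lists changed there. The serotonergic list was at -0.92 (percentile 0.640, 7 of 9 lower) and the oligodendrocyte lineage list at -0.69 (percentile 0.510, 14 of 17 lower). With the lowest class at 0 the oligodendrocyte lineage list was at -0.41, inside the random lists at percentile 7.34. The serotonergic list was then outside, at percentile 2.265, but inside random lists also matched on span, at percentile 3.685. Mbp, a myelin protein gene, had -1.80. The reactive astroglia list was at 0.59 (percentile 98.7, 7 of 10 higher), with Stat3 at 2.47, Steap4 at 1.57 and Cd44, a receptor gene for hyaluronan, at 0.99. The stratified epithelium list was at 0.81 (percentile 98.2, 5 of 7 higher), with Perp, a desmosome gene, at 3.07 and Trp63, a regulator of epidermis, at 1.24. With the lowest class at 0 the epithelium list was at 0.73, just inside the central 95% of random lists. As deposited, no other list lay outside it. The GABAergic list was at -0.39 (percentile 11.1), and with the lowest class at 0 at -0.63 (percentile 4.25, 2.08 of lists matched on span), and the glutamatergic list was as deposited at -0.18 (percentile 20.1).

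The pan-neuronal median log2 ratio with BMS961+BMS641 was -0.70 (-0.73 to -0.49), with Snap25 at -1.11 and Gap43, which encodes a protein of growth cones, at -1.10. The astroglia median was -0.50 (-0.72 to -0.06), or -0.25 relative to all genes and 0.01 with the lowest class at 0, with 12 of 17 genes lower, and Slc1a2, a glutamate transporter gene, had -1.79. The difference of the medians, -0.20, was smaller than its standard deviation over the pairs of quadrants (0.24). As the share of positive spots Gap43 had 0.53, and with no scaling to ppm the astroglia median was 0.04.

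The highest ratios with BMS961+BMS641 were those of Cym (7.99), Rapsn (7.48), Cpa3 (6.67), Irgm2 (6.43), Sowahc (6.22), Epcam (6.20), Grxcr2 (6.14) and Riok1 (6.09). Cym encodes a gastric protease, Rapsn a protein that clusters acetylcholine receptors at the nerve-muscle junction, Cpa3 a mast cell protease and Epcam an epithelial adhesion protein. Epcam was at 921 ppm against 11.5 ppm and above the lowest class in 98.6% of spots against 19.6%. The lowest ratios were those of Mocs2 (-7.25), Psmd9 (-7.18), Pgls (-6.90), Zfp239 (-6.37), Atp6v0b (-6.27), Txndc11 (-6.19), Tsga10ip (-6.06) and Plpp2 (-6.03). Rara had -0.21, Rarb -0.22, Rarg -0.95, Tubb3 -0.44, Map2 -0.38, Slc1a3 -0.50, Gfap -1.74, Mki67 -2.72 and Pou5f1 -0.15.

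**Figure D2:**
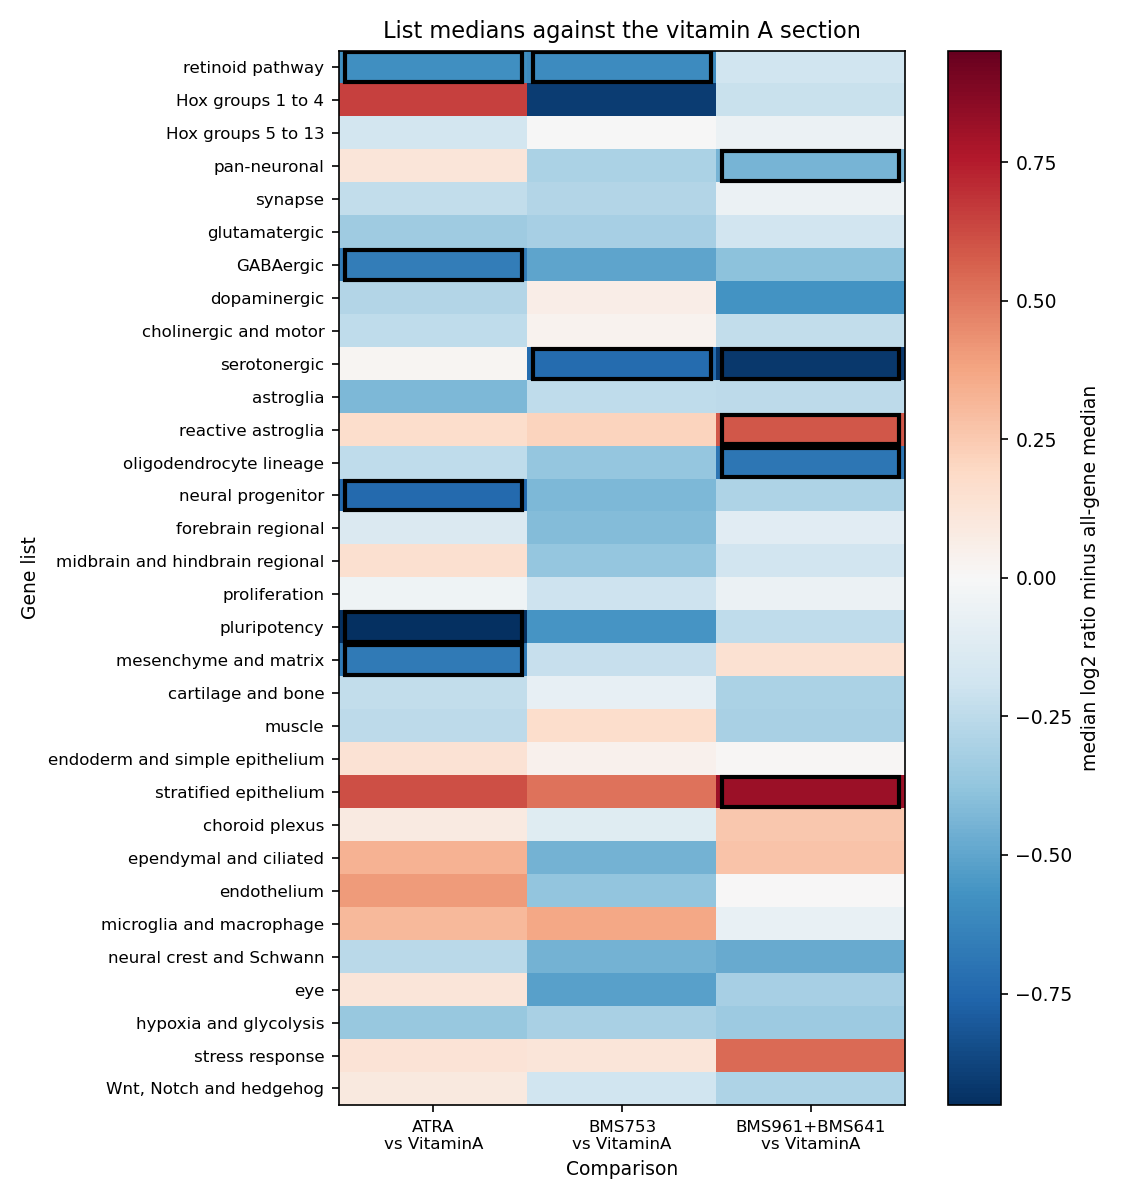
Median log2 ratio of each gene list minus the all-gene median (colour) in the comparisons with the VitaminA section (columns), where boxes mark lists outside the central 95% of random lists. The retinoid pathway list is boxed with ATRA (-0.58) and BMS753 (-0.60), and the reactive astroglia list with BMS961+BMS641 (0.59).

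**Figure D3:**
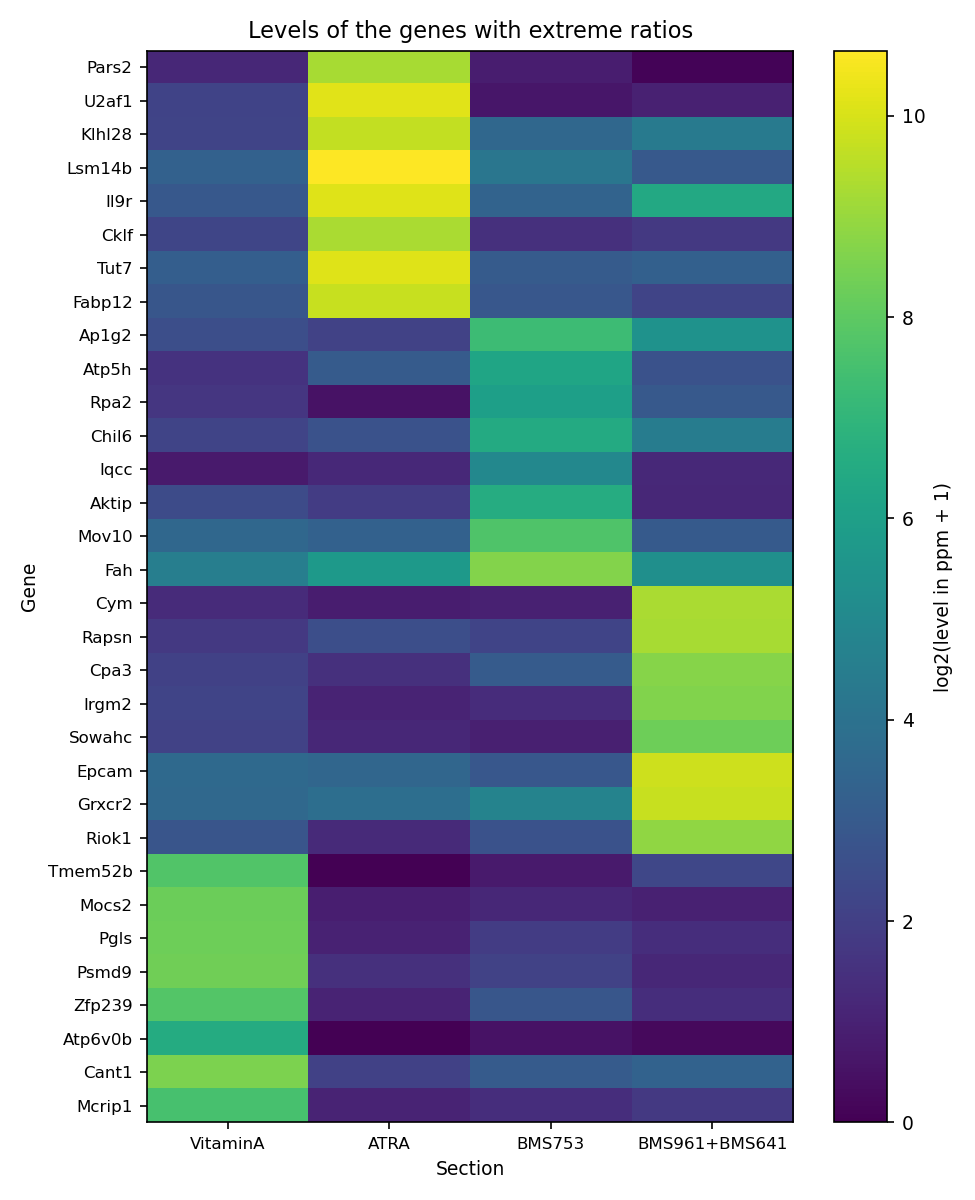
Levels as log2 of ppm plus 1 (colour) in each section (columns) of the genes with the highest ratios of each ligand section and the lowest of ATRA against VitaminA. Pars2 is high in ATRA (603 ppm), Cym in BMS961+BMS641 (622 ppm) and Mocs2 in VitaminA (302 ppm).

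The ligand sections were also compared with each other, to ask whether the receptor that is activated matters. Between BMS753 and ATRA, which were given at the same dose, Hoxb3 was low (-3.73) and so were Stat3 (-4.75), Osmr (-4.64) and Mlc1 (-3.14), each of them high with ATRA. Stmn2 (1.60) and Slc1a3 (1.54) were higher with BMS753, but as the share of positive spots Slc1a3 had -0.12, Tubb3 -0.01 and Klk11 -1.21. The median over the 14902 genes compared was 0.71. Hox groups 1 to 4, which pattern the hindbrain, were at -0.72 relative to it (percentile 1.97, 6 genes), at -1.46 with the lowest class at 0 (percentile 0.740, 5 genes), but at percentile 7.49 of random lists also matched on span. All 12 measured GABAergic genes and all 10 pluripotency genes were higher with BMS753, at 0.25 and 0.02 relative to all genes (percentiles 89.5 and 54.9). The pan-neuronal median was 0.49 (0.29 to 0.91) and the astroglia median 0.62 (0.43 to 1.21), or -0.23 and -0.09 relative to all genes, and their difference was -0.14 (standard deviation 0.30). The highest ratios were those of Rpa2 (5.47), Ap1g2 (5.17), Hint2 (4.88), Sytl4 (4.77), Aktip (4.71), Rhbdd2 (4.57), Klk11 (4.48) and Mov10 (4.41), and the lowest those of U2af1 (-9.51), Pars2 (-8.38), Cklf (-7.82), Olfr724 (-7.48), Tut7 (-7.10), Psen2 (-7.03), Pank2 (-6.87) and Fabp12 (-6.86). Rara had 0.49, but -0.22 once centred on all genes, Rarb 0.30, Rarg 1.11, Tubb3 1.15, Map2 1.39, Mki67 1.33 and Pou5f1 0.38. Gfap, below the 5 ppm filter in both sections, had -0.32.

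Between BMS961+BMS641 and ATRA, given at different doses, Stmn2 (5.29), Gad1 (3.45), Gria3 (3.25), Crabp1 (3.83) and Elavl4 (1.85) were higher with the pair. Osmr (-5.33), Mlc1 (-4.60), Hoxb3 (-3.71) and Htr2c, a serotonin receptor gene (-3.14), were lower. The median over the 13732 genes compared was 0.04. Relative to it, the serotonergic list was at -0.68 (percentile 1.96) and the Wnt, Notch and hedgehog list at -0.52 (percentile 0.735), which with the lowest class at 0 were at -0.76 and -0.61, no smaller, yet inside the random lists at percentiles 4.24 and 2.99. In that setting the stress response list at 1.13 (percentile 99.6) and the Hox groups 1 to 4 list at -1.24 (percentile 1.97) lay outside them. Neither did when the random lists were also matched on span. Of the Wnt, Notch and hedgehog list, Nkd1, an antagonist of Wnt signalling, had -3.88 and Shh, the sonic hedgehog gene, -3.58. The pan-neuronal median was -0.01 (-0.27 to 0.29) and the astroglia median 0.27 (-0.15 to 0.51). Without scaling to ppm these medians were 0.80 and 1.01. Their difference was -0.28 (standard deviation 0.23), but -0.04 with only genes of at least 20 ppm and 0.05 as the share of positive spots. The highest ratios were those of Cym (8.42), Mtag2 (8.36), Grpel2 (7.79), Wfdc17 (7.69), Riok1 (7.61), Irgm2 (7.58), Cpa3 (7.26) and Sowahc (7.12), and the lowest those of U2af1 (-9.16), Pars2 (-9.12), Fam183b (-8.55), Lsm14b (-7.66), Psen2 (-7.62), Fabp12 (-7.57), Manbal (-7.51) and Siae (-7.51). Rara had 0.69, Rarb 0.01, Rarg 0.79, Tubb3 -0.01, Map2 1.26, Slc1a3 0.03, Mki67 0.01 and Pou5f1 0.08. Gfap, below the 5 ppm filter in both sections, had -1.52.

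Between BMS753 and BMS961+BMS641, also given at different doses, Crabp1 (-5.64), Stmn2 (-3.69), Stat3 (-2.80) and Gad1 (-2.29) were lower with BMS753. Tgm2 (2.57) and Slc1a3 (1.52) were higher, but as the share of positive spots Tgm2 had -0.05, Slc1a3 -0.13, Tubb3 -0.01 and Klk11 -1.06. The median over the 14973 genes compared was 0.64. Of the proliferation list, 11 of 14 genes were higher with BMS753, but its median was at -0.48 relative to all genes (percentile 1.84; -0.39 and percentile 4.32, inside the random lists, with the lowest class at 0), with Mcm6, a gene of the DNA replication helicase, at -1.57 and Ccnb2, a mitotic cyclin gene, at 1.40. With the lowest class at 0, the reactive astroglia list lay outside the random lists, at -0.70 (percentile 1.43). The pan-neuronal median was 0.39 (0.13 to 0.73), the astroglia median 0.48 (0.13 to 0.86), which are -0.25 and -0.17 relative to all genes, and their difference -0.08 (standard deviation 0.31). Among the highest ratios were those of Aktip (5.42), Hint2 (4.81), Klk11 (4.73), Mov10 (4.70), Ptafr (4.62), BC049762 (4.20) and Cgn (4.15), and the lowest those of Cym (-8.30), Grpel2 (-8.03), Wfdc17 (-7.58), Mtag2 (-7.52), Sowahc (-7.37), Irgm2 (-7.27), Rapsn (-7.07) and Epcam (-6.97). Rara had -0.20, Rarb 0.28, Rarg 0.32, Tubb3 1.16, Map2 0.13, Mki67 1.32 and Pou5f1 0.30. Gfap, below the 5 ppm filter in both sections, had 1.20.

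**Figure D4:**
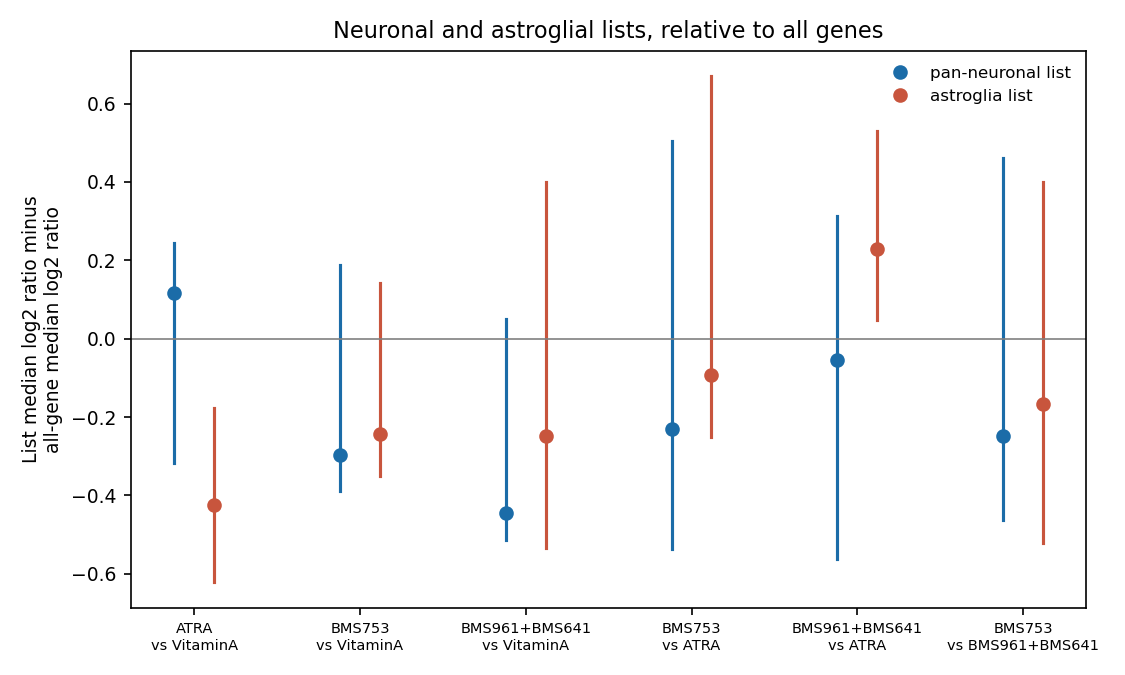
Median log2 ratio of the pan-neuronal and astroglia lists minus the all-gene median (vertical axis) in each comparison (horizontal axis), where points are whole sections and lines the range over the 16 pairs of quadrants. With ATRA against VitaminA the neuronal list is at 0.12 and the astroglia list at -0.43.

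Over the 6 comparisons, 16 of 192 list medians lay outside the central 95% of random lists, where 9.6 would by chance. The lists share genes and the comparisons share sections, so these medians are not independent. With the lowest class at 0, 6 of the 16 stayed outside on the same side, among 11 lists outside in that setting.

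Within sections, spots rich in neuronal signal were also rich in astroglial signal, as was true of random lists. Over spots, which are not independent replicates, the Spearman correlation of the list scores was 0.561 in VitaminA, 0.769 in ATRA, 0.680 in BMS753 and 0.749 in BMS961+BMS641. The median pair of random lists gave 0.556, 0.818, 0.727 and 0.788. Each spot carries a factor that scales all of its values. With this factor divided out, the correlations were 0.296, 0.186, 0.198 and 0.0470, and the highest of the random pairs were 0.263, 0.540, 0.446 and 0.418. From tie classes the correlations were 0.698, 0.745, 0.774 and 0.774, and the highest of the random pairs 0.713, 0.743, 0.758 and 0.801. Moran's I, which is positive when neighbouring spots are alike, was 0.238 in VitaminA, 0.338 in ATRA, 0.228 in BMS753 and 0.397 in BMS961+BMS641 for the pan-neuronal list. For the astroglia list it was 0.129, 0.285, 0.235 and 0.310. Random lists of like level had medians of 0.259, 0.351, 0.339 and 0.425 beside the neuronal list and 0.185, 0.319, 0.330 and 0.381 beside the astroglia list. As deposited, neither list was more clustered than its median random list in any section. With the spot factor divided out, Moran's I of the pan-neuronal list was 0.146, 0.122, 0.211 and 0.0989, above the random medians of 0.0450, 0.0414, 0.0385 and 0.0215, and 2, 18, 11 and 8 of 100 random lists reached it. For the astroglia list it then was 0.0396, 0.0495, -0.0039 and -0.0045, which 43, 65, 86 and 86 random lists reached. From tie classes, 81, 51, 2 and 0 random lists reached the pan-neuronal value and 44, 2, 20 and 33 the astroglia value, so the clustering depends on the values used.

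Spots of each section were grouped into 4 regions, of which the most frequent held 31.9% in VitaminA, 29.0% in ATRA, 31.6% in BMS753 and 31.2% in BMS961+BMS641. In VitaminA, a region led by Nfe2, Ccdc189, Meox2 and Kdr, an endothelial growth factor receptor gene, held 131 spots, and Kdr was above the lowest class in 30.5% of them against 17.3% of the others. In ATRA, a region led by Lclat1, Kcnip3 and Cemip2 held 129 spots, with Kcnip3, a calcium sensor gene, above the lowest class in 59.7% against 30.6%. In BMS753, a region led by Dusp8, Polb, Cib2 and Rnf216 held 58 spots, with Rnf216, a ubiquitin ligase gene, in 72.4% against 35.5%. In BMS961+BMS641, a region led by Nnmt, Slc25a16 and Chd1l held 60 spots, but 98.8% of the Nnmt signal of the section came from a single pair of spots. In most regions the first leading gene likewise drew most of its signal from such a pair. Each region described is the region of its section with most genes above the lowest class, a median of 5831, 4653, 5508 and 6336 per spot, so any gene tends to be seen more often there. Quartiles of that number matched the regions with an adjusted Rand index between 0.0917 and 0.184. The regions also differed in the spot factor, whose quartiles matched them with an adjusted Rand index between 0.0959 and 0.214.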

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

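Settings chosen only after the data were seen were the lowest class at 0, tie class indices, centring within bins of level and span, leaving out the top 10 genes, dividing out the spot factor (within sections only), and random lists also matched on span, alone or with the lowest class at 0. No paired analysis was possible because each group has a single section. Values are called alike when they moved by less than the standard deviation over quadrants. Of 138 alternative values each, 106 neuronal medians, 108 astroglial medians and 124 of their differences were alike, and 24, 22 and 14 moved. The other 8, 8 and 0 turned a sign that all 16 pairs of quadrants shared. Further changes of sign are counted as moved or alike. The difference in BMS753 against ATRA, for example, went from -0.14 to 0.27 after quantile normalization of the sections. Of 7517 values of named genes, 6229 were alike, 1243 moved and 45 turned their sign, the last counted only where the quadrants of the sections lay apart. These cover the lists described by their members, a choice made after the values were seen; over members of all lists more values turned. The number of lists outside the central 95% of random lists was 16, 18 with lists matched on span and 11 with the lowest class at 0. Of the latter, 6 are among the 16. The others are the microglia and macrophage list in ATRA against VitaminA (0.61, percentile 98.5), the GABAergic list in BMS753 against VitaminA (-0.92, percentile 0.100), the Hox groups 1 to 4 list in BMS961+BMS641 against ATRA (-1.24, percentile 1.97), the stress response list in BMS961+BMS641 against ATRA (1.13, percentile 99.6), the reactive astroglia list in BMS753 against BMS961+BMS641 (-0.70, percentile 1.43), each median relative to all genes. When random lists were also matched on span, the microglia and macrophage, Hox groups 1 to 4 and stress response lists lay inside them. Of the 6, so did the pluripotency list in ATRA against VitaminA and the serotonergic list in BMS961+BMS641 against VitaminA. The Hox groups 1 to 4 list in BMS753 against ATRA did too. With both settings together the number was 6, below the 9.6 that chance gives. No read or molecule counts were at hand, so which differences lie within counting error is unknown.

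Without scaling to ppm, the neuronal median was -0.51 in ATRA against VitaminA, -0.41 in BMS753 against VitaminA, -0.15 in BMS961+BMS641 against VitaminA, 0.80 in BMS961+BMS641 against ATRA and -0.62 in BMS753 against BMS961+BMS641. The astroglial median then was -0.93 in ATRA against VitaminA, -0.34 in BMS753 against VitaminA, 0.0402 in BMS961+BMS641 against VitaminA, 1.01 in BMS961+BMS641 against ATRA and -0.54 in BMS753 against BMS961+BMS641. The missing scaling turned the sign of Hoxa3 (-0.25) and Osmr (-0.28) in BMS753 against BMS961+BMS641. Centred on the all-gene median, the neuronal median was 0.12 in ATRA against VitaminA, -0.30 in BMS753 against VitaminA, -0.45 in BMS961+BMS641 against VitaminA, -0.23 in BMS753 against ATRA and -0.25 in BMS753 against BMS961+BMS641. Its astroglial counterpart was -0.43 in ATRA against VitaminA, -0.24 in BMS753 against VitaminA, -0.25 in BMS961+BMS641 against VitaminA, -0.0938 in BMS753 against ATRA and -0.17 in BMS753 against BMS961+BMS641. This centring turned the sign of Rarb (0.0980) in ATRA against VitaminA. This centring turned the sign of Esrrb (-0.0133) and Rara (-0.22) in BMS753 against ATRA. After quantile normalization of the sections to each other, the neuronal median was -0.50 in BMS961+BMS641 against VitaminA and 0.0841 in BMS753 against BMS961+BMS641. For astroglia the median was -0.32 in ATRA against VitaminA, -0.18 in BMS753 against VitaminA, -0.21 in BMS961+BMS641 against VitaminA, 0.11 in BMS753 against ATRA and 0.0926 in BMS753 against BMS961+BMS641. The neuronal minus astroglial difference then was 0.15 in ATRA against VitaminA and 0.27 in BMS753 against ATRA. It turned the sign of Rara (-0.0341) in BMS753 against ATRA. With a pseudocount of 10 ppm, the neuronal median was -0.44 in BMS961+BMS641 against VitaminA, 0.33 in BMS753 against ATRA and 0.23 in BMS753 against BMS961+BMS641. The astroglial median then was -0.40 in ATRA against VitaminA and -0.26 in BMS961+BMS641 against VitaminA. The difference of the medians was 0.29 in ATRA against VitaminA. With no filter on low genes, the neuronal median was -0.43 in ATRA against VitaminA and -0.19 in BMS753 against VitaminA. Its astroglial counterpart was 0.0791 in BMS961+BMS641 against ATRA. Neuronal minus astroglial, it was 0.32 in ATRA against VitaminA. With a filter at 20 ppm, the neuronal median was -0.43 in ATRA against VitaminA. For astroglia the median was -0.47 in ATRA against VitaminA and 0.0316 in BMS961+BMS641 against ATRA. The neuronal minus astroglial difference then was 0.0388 in ATRA against VitaminA and -0.0428 in BMS961+BMS641 against ATRA. As the share of positive spots, the neuronal median was -0.0479 in BMS961+BMS641 against VitaminA, -0.0316 in BMS753 against ATRA and -0.17 in BMS753 against BMS961+BMS641. The astroglial median then was -0.26 in ATRA against VitaminA, 0.0994 in BMS961+BMS641 against VitaminA, 0.0000 in BMS753 against ATRA, 0.0102 in BMS961+BMS641 against ATRA and -0.19 in BMS753 against BMS961+BMS641. The difference of the medians was 0.16 in ATRA against VitaminA and 0.0542 in BMS961+BMS641 against ATRA. This share turned the sign of Hoxd3 (0.73), Abat (0.41), Notch1 (1.18), Cenpf (1.43), Sall4 (0.0990), Tfcp2l1 (0.68), Lum (0.23) and Col5a1 (0.0052) in ATRA against VitaminA. It turned the sign of Hoxd3 (0.20), Notch2 (-0.0559) and Tfcp2l1 (0.25) in BMS753 against VitaminA. It turned the sign of Gap43 (0.53), Tph2 (0.33), Cspg4 (0.67), Enpp6 (0.51) and Sall4 (0.0071) in BMS961+BMS641 against VitaminA. It turned the sign of Klk11 (-1.21), Tgm2 (-0.0613), Rxra (-0.67), Slc17a8 (-0.0136), Abat (-0.66), Slc1a3 (-0.12), Notch1 (-0.0798), Sall4 (-1.46) and Tubb3 (-0.0122) in BMS753 against ATRA. It turned the sign of Klk11 (-1.06), Tgm2 (-0.0546), Aldh1a3 (-0.0466), Hoxa3 (-0.0061), Rbfox3 (-0.0501), Calb2 (-0.0878), Slc1a3 (-0.13), Slc1a2 (-0.0792), Osmr (-0.23), Sall4 (-1.36), Lin28a (-0.0030) and Tubb3 (-0.0122) in BMS753 against BMS961+BMS641. Without the top 1% of spots of each gene, the neuronal median was -0.48 in ATRA against VitaminA and 0.65 in BMS753 against ATRA. Neuronal minus astroglial, it was 0.40 in ATRA against VitaminA. Without quadrant 1 of VitaminA, the neuronal minus astroglial difference was 0.39 in ATRA against VitaminA. Without quadrant 2 of ATRA, the neuronal median was -0.42 in ATRA against VitaminA. The neuronal minus astroglial difference then was 0.37 in ATRA against VitaminA. Without quadrant 4 of ATRA, the neuronal median was -0.34 in ATRA against VitaminA. The difference of the medians was 0.34 in ATRA against VitaminA. As tie class indices, the neuronal median was -0.35 in ATRA against VitaminA and -0.60 in BMS961+BMS641 against VitaminA. Neuronal minus astroglial, it was 0.29 in ATRA against VitaminA. Centred within bins of level and span, the neuronal median was -0.23 in BMS753 against VitaminA, -0.39 in BMS961+BMS641 against VitaminA, -0.16 in BMS753 against ATRA and -0.13 in BMS753 against BMS961+BMS641. Its astroglial counterpart was -0.25 in ATRA against VitaminA, -0.36 in BMS753 against VitaminA, -0.24 in BMS961+BMS641 against VitaminA, -0.0804 in BMS753 against ATRA and -0.29 in BMS753 against BMS961+BMS641. The neuronal minus astroglial difference then was 0.11 in ATRA against VitaminA. These bins turned the sign of Rarb (0.0258) in ATRA against VitaminA. These bins turned the sign of Rara (-0.18) in BMS753 against ATRA. Without quadrant 1 of BMS961+BMS641, the neuronal median was -0.60 in BMS961+BMS641 against VitaminA. With 4 neighbours, Moran's I was 0.318 in ATRA for the astroglia list. With the spot factor divided out, Moran's I was 0.146 in VitaminA, 0.122 in ATRA and 0.0989 in BMS961+BMS641 for the pan-neuronal list, and 0.0396 in VitaminA, 0.0495 in ATRA, -0.0039 in BMS753 and -0.0045 in BMS961+BMS641 for the astroglia list. The correlation of the neuronal and astroglial scores was 0.296 in VitaminA, 0.186 in ATRA, 0.198 in BMS753 and 0.047 in BMS961+BMS641. The most frequent region held 37.0% in VitaminA and 37.3% in ATRA. From tie classes, Moran's I was 0.324 in VitaminA and 0.470 in BMS753 for the pan-neuronal list, and 0.256 in VitaminA, 0.338 in ATRA and 0.378 in BMS753 for the astroglia list. The correlation of the neuronal and astroglial scores was 0.698 in VitaminA and 0.774 in BMS753. With k = 3, the most frequent region held 41.1% in VitaminA, 38.8% in ATRA, 41.4% in BMS753 and 37.8% in BMS961+BMS641. With k = 6, the most frequent region held 19.9% in VitaminA, 24.8% in ATRA, 23.5% in BMS753 and 21.6% in BMS961+BMS641.

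With the lowest class at 0, these lists no longer lay outside the random lists, and their medians relative to all genes (range over pairs of quadrants) went closer to 0: retinoid pathway in ATRA against VitaminA from -0.58 (-0.80 to -0.20) to -0.33 (-0.47 to 0.01), neural progenitor in ATRA against VitaminA from -0.74 (-0.93 to -0.35) to -0.62 (-1.29 to -0.39), mesenchyme and matrix in ATRA against VitaminA from -0.67 (-0.99 to -0.07) to -0.34 (-0.74 to 0.05), serotonergic in BMS753 against VitaminA from -0.73 (-1.05 to -0.06) to -0.44 (-0.63 to 0.00), pan-neuronal in BMS961+BMS641 against VitaminA from -0.45 (-0.51 to 0.05) to -0.22 (-0.37 to 0.02), oligodendrocyte lineage in BMS961+BMS641 against VitaminA from -0.69 (-1.06 to 0.02) to -0.41 (-0.99 to 0.08), stratified epithelium in BMS961+BMS641 against VitaminA from 0.81 (0.35 to 1.18) to 0.73 (-0.11 to 1.04), proliferation in BMS753 against BMS961+BMS641 from -0.48 (-0.61 to 0.04) to -0.39 (-0.72 to 0.19). The all-gene median itself went from -0.33 to -0.60 in ATRA against VitaminA, and from -0.25 to -0.52 in BMS961+BMS641 against VitaminA. Before it was subtracted, the retinoid pathway median with ATRA went from -0.91 to -0.93 and the neural progenitor median from -1.07 to -1.22. With BMS961+BMS641 the pan-neuronal median went from -0.70 to -0.74, but that of stratified epithelium from 0.56 to 0.22. Relative to all genes, the serotonergic median in BMS961+BMS641 against ATRA went further from 0, from -0.68 (-1.26 to -0.18) to -0.76 (-1.25 to -0.55). So did that of the Wnt, Notch and hedgehog list there (-0.52 to -0.61), yet both lay inside the random lists. The median of Hox groups 1 to 4 in BMS753 against ATRA from -0.72 (-1.10 to -0.49) to -1.46 (-2.89 to -0.48) also went further from 0 and stayed outside, but lay inside the random lists when these were matched on span.

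Centring on the all-gene median shifts all ratios of a comparison by a constant, by construction. The share of positive spots counts ties split by gene order as positive. For the other settings the cause was not tested.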

Other observations

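The tests of mature messenger RNA, of the authors' normalization and of gene length bias were chosen only after the result was seen, as were the values of Moran's I from tie classes or with the spot factor divided out. Neither of the forms in which the normalization was tested on single genes decides anything, because the way their genes were picked fixed the outcome.

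As deposited, the lists given next lay inside the central 95% of random lists of like level. With BMS753 against VitaminA, all 8 measured stratified epithelium genes were higher, with a median of 0.51 relative to all genes at percentile 92.3, but 4 of 7 were with the lowest class at 0 (0.38, percentile 86.1). With BMS961+BMS641 against VitaminA, the stress response list was at 0.54 (percentile 97.3), but at 0.11 with the lowest class at 0 (percentile 81.9), and at percentile 83.1 of random lists matched on span. Against ATRA it was at 0.09 (percentile 52.2), and at 1.13 with the lowest class at 0, there outside the random lists (percentile 99.6), but inside those also matched on span. The neural crest and Schwann list was, with BMS961+BMS641 against VitaminA, at -0.48 (percentile 3.21, 1.80 of lists matched on span) and at -0.39 with the lowest class at 0 (percentile 7.27). With ATRA against VitaminA, the Hox groups 1 to 4 list was at 0.65 (percentile 94.5), and at 0.89 with the lowest class at 0, also inside. With BMS753 against ATRA, 11 of 12 dopaminergic genes were higher, with a median of 0.31 relative to all genes (percentile 96.7), and 0.42 with the lowest class at 0 (percentile 93.2).

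In space, genes of Hox groups 5 to 13, which pattern the trunk, had a Moran's I of 0.0718 in VitaminA, 0.297 in ATRA, 0.411 in BMS753 and 0.426 in BMS961+BMS641, which 67, 18, 1 and 0 of 100 random lists reached. With the spot factor divided out, 80, 14, 0 and 0 did so, and from tie classes 94, 88, 93 and 50. The stress response list had 0.112, 0.302, 0.417 and 0.402, which 12, 3, 2 and 1 random lists reached. Its values with the spot factor divided out were reached by 21, 2, 2 and 0, and those from tie classes by 56, 59, 52 and 98. Tie classes undo the split of ties, drop the spot factor and replace values by ranks at once, so which of these matters was not tested.

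The first pattern is that gene levels followed genomic span in every section. Mature messenger RNA as the main source would place abundant transcripts far above genes of like span, but their median percentile was 66.9, 56.3, 56.8 and 41.8, at most 66.9. How reads shared between genes were counted is not given. Their loss, not tested, would lower abundant transcripts that have such reads, so this value alone cannot settle the source. Genomic DNA as the main source may explain the pattern: neuronal genes and genes of other tissues would be seen equally often at equal span. Their log2 percent of spots differed by 0.274, 0.138, 0.00787 and -0.0879, at most 0.274. Against it, the 635 to 897 olfactory and vomeronasal receptor genes of a section had median percentiles of 26.0, 31.3, 31.3 and 34.3 among genes of like span, although reads shared between these paralogs, not tested, would lower them too, so genomic DNA and transcripts cannot be told apart here. Priming within introns of nuclear RNA was not tested, nor was any biological explanation, since the pattern was in all groups.

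The second pattern is a set of 141 genes seen in at least 80% of spots of a section and at most 20% of each other, 31 in VitaminA, 48 in ATRA, 0 in BMS753 and 62 in BMS961+BMS641. The authors' normalization stays open: genes picked for a high ratio had a median log2 ratio of 5.26 with the lowest class at 0, but that undoes the split of ties alone and could hardly lower the ratio. Copy number of the chromosome region is argued against by the 459 flanking genes, whose median relative ratio was 0.0282. Uneven amplification of single loci in a library is a candidate explanation. The Moran's I of these genes had median percentiles of at most 69 among genes of like level. These genes were picked for presence in most spots and their references were not, which may itself favour a low value, so this decides little. Even expression over the section, as a response to the ligand, would look alike and stays open, since each group is a single section.

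The third pattern is the set of 16 list medians outside the central 95% of random lists. A few section-wide genes are argued against as the whole cause. Only 3 of these lists hold any, and all of them stayed outside without such genes, at percentiles 0.97, 0.99 and 1.10. In all 15 stayed outside, but for lists that hold none only the random lists changed. Gene length bias stays open: 15 stayed outside when random lists were also matched on span, but of the 11 outside with the lowest class at 0 only 5 did. The authors' normalization stays open too: with the lowest class at 0, 6 stayed outside, but some lists that no longer did kept medians about as large, such as the serotonergic list in BMS961+BMS641 against ATRA (-0.68 to -0.76). A response to the ligands stays open and untested, as group and section are the same.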
